A study of Mus musculus with 16 samples.

How the data were processed

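Total RNA of whole BALB/c lungs was amplified, labelled with Cy3 and hybridized to Agilent one-colour mouse arrays, per the labels. The 16 arrays form 4 groups of 4, RSV or mock at 6 weeks or 6 days of age, and the series states 4 biological replicates per condition. Groups were taken from the sample labels. Sex is not labelled.

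The deposited scanner files hold spot intensity, and per the file headers gProcessedSignal is an intensity with background subtracted and spatial trends removed within each array. Per the file headers the 6-week arrays were read with a G2505C scanner in a single range and Feature Extraction 10.7.3.1, and the 6-day arrays with a G2505B scanner in extended range and version 10.5.1.1. The 6-week arrays came from 4 slides, each with 1 RSV and 1 mock array, and the 6-day arrays from 2 slides, each with 2 of each. The value table deposited by the authors is on the log2 scale, and it was found to equal log2 of the median spot signal minus a constant per array, with column medians from -0.081 to -0.036; it was used only as an alternative. No coordinates are given because the genome builds named in the file headers differ between the ages.

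Values were log2 of gProcessedSignal minus the 75th percentile of non-control spots of the array, with spots of a probe averaged. Of 41174 probes, 27198 were named by accession, 5585 by symbol, 719 by an older symbol and 1374 by the name in the files, and 6298 had no name. The brightest probe represented each gene. Genes well above background on at least 3 of 4 arrays in at least 1 group were tested, which gave 16787 genes of 21180. The share of spots well above background stands for depth, and the number of arrays limits the precision.

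A limma means model over the 4 groups was fitted to all 16 arrays, with 12 residual degrees of freedom. All groups share its spread, though the median SD of a gene was 0.114 in 6-week mock and 0.177 in 6-week RSV lungs. In 6-day lungs it was 0.246 with mock and 0.159 with RSV. With only the 8 arrays of an age, 2494 genes passed at 6 weeks and 4189 at 6 days, in place of 1376 and 6579. The sizes of the counts at the ages therefore depend on this choice. Contrasts were RSV minus mock at each age, the difference of these responses (6 days minus 6 weeks), and 6-day minus 6-week mock lungs. Adjusted p-values are Benjamini-Hochberg values over the tested genes of a contrast, with a threshold of 0.05. "At least" folds are measured against background where a group was below it on all arrays. The software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

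Before the data were examined 31 gene lists were fixed: interferon-stimulated genes, interferon-γ-induced genes, interferons and their receptors, virus sensing, inflammatory cytokines and chemokines, acute phase and airway defence, type 2 immunity, dendritic cells, MHC class I and II pathways, T cells, NK cells, B cells, neutrophils, macrophages, eosinophils with basophils and mast cells, airway cells, alveolar epithelium, endothelium, mesenchyme, cell cycle, imprinted genes, regulatory genes, erythroid cells, muscle, thymus, fat, liver, clock genes, stress genes and sex-linked genes. The sex-linked list served as a check, and the other 30 were tested. The list given as imprinted genes holds imprinted and fetal growth genes. The erythroid, muscle, thymus, fat, liver, clock and stress lists were also meant as checks of sample make-up. Cell type lists describe marker RNA in whole lung, not cell numbers. Lists were tested with camera (correlation 0.01), camera with an estimated correlation, and fry, each adjusted over the 30 lists. camera asks whether a list moved more than other genes, and fry whether its genes moved on balance one way. List scores, the mean of the list on each array, were compared by exact two-sided permutation tests. For the difference of responses, labels were exchanged within each age, so that test refers to no infection effect at either age, not to equal responses.

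The rule for named genes, fixed before the data were examined, took 3 parts for each contrast. These were the 6 largest rises and 6 largest falls among passing genes with groups that did not overlap and signal above background on all arrays of the higher group; up to 4 members of each list with the smallest adjusted p; and a fixed set that includes Irf7, Isg15, Mx1, Ifit1, Oas1a, Cxcl10, Il6, Ccl2, Cxcl1, Ifng, Il13, Il33, Flt3, Siglech and Itgax. The text names a part of these genes, picked after their values were seen; stability was counted over 332 gene results, whether or not the text names them.

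The other settings fixed in advance were quantile normalization, the deposited value table, no filter, a filter on all 16 arrays, the mean of all probes of a gene, only the 8 arrays compared, slide as a block, replicate number as a block, trend and robust variance, a 2-fold minimum, and leaving out each array. Gene and list calls at each age were recomputed under 25 of these settings, both under 24 for the difference of responses, and for age genes under 25 and lists under 24. A gene that a filter removed has 1 setting fewer, and "lost in" counts refer to them. After seeing the data, normexp background correction of the median signal (offset 50), the 28S signal and the Xist signal as covariates, array weights (estimated gene by gene because the REML estimate did not converge), and leaving out the arrays standing apart together were added. Pairing was checked from correlations of residuals: same-number pairs at 6 days gave 0.284, 0.157, 0.135 and 0.135 but shared slides, and at 6 weeks 0.101, 0.024, -0.09 and 0.152, so arrays were treated as unpaired.

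The fit was tested on simulated data with 200 changed genes. It recovered 71.6% of genes changed by log2 1 at 6 weeks, 76.1% at 6 days, 59.7% for the difference of responses and 68.7% for age. With no simulated change 0 genes were called. In the runs with 200 changed genes, 6 unchanged genes were called at 6 weeks and 9 at 6 days. For the difference of responses 2 were called, and for age 4. Other splits of the real 6-day arrays gave from 0 to 3986 genes. The simulated 0 therefore cannot be taken as the number of false calls on the real arrays.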

Results

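Gene expression was measured in whole lungs of BALB/c mice, an inbred laboratory strain, infected with respiratory syncytial virus (RSV) or given a mock inoculum. The 16 one-colour arrays fall into 4 groups of 4 arrays, RSV and mock at 6 weeks and RSV and mock at 6 days of age. Lungs were taken 2 days after inoculation, and the labels leave open whether the stated age is that at infection or at sampling. The series title names the neonatal lung, dendritic cells and type I interferon. Between 67.3% and 77.9% of spots were well above background on 15 of the arrays, and 90.1% were on 6-day mock replicate 3. Of 21180 gene symbols on the array, 16787 were tested, and the number of arrays limits the precision of every value. Errors are limma standard errors with n = 4 arrays per group unless stated. The 6-week and 6-day arrays were on different slides, read by different scanners and software versions, so age cannot be told apart from array batch in mock lungs. Each response to infection was measured within its own batch.

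Several properties of the lungs differed beside the planned groups. The probe for 28S ribosomal RNA, a transcript with no poly(A) tail, read 2.11 ± 0.82 (SD, n = 4) in 6-week mock lungs and 4.34 ± 0.43 in 6-week RSV lungs on the normalized log2 scale. In 6-day lungs it read 6.91 ± 0.64 with mock and 3.11 ± 1.68 with RSV, so it moved in opposite directions with infection at the ages compared. RSV and mock arrays did not overlap at either age. The highest 6-week mock value was 3.17 and the lowest 6-week RSV value 3.79. At 6 days the highest RSV value was 5.38 and the lowest mock value 6.13. A loss of calls with this signal as a covariate therefore cannot separate infection from what the 28S probe follows. Xist was low and the Y-linked genes Ddx3y and Eif2s3y were high on 6-week RSV replicates 1 and 3, 6-day RSV replicate 1 and 6-day mock replicate 4, the pattern of male mice, and the other 12 arrays had the female pattern. The neutrophil score of 6-week RSV replicate 1 was 1.54, whereas the other arrays of its group had scores from -1.88 to -1.11.

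**Figure D1:**
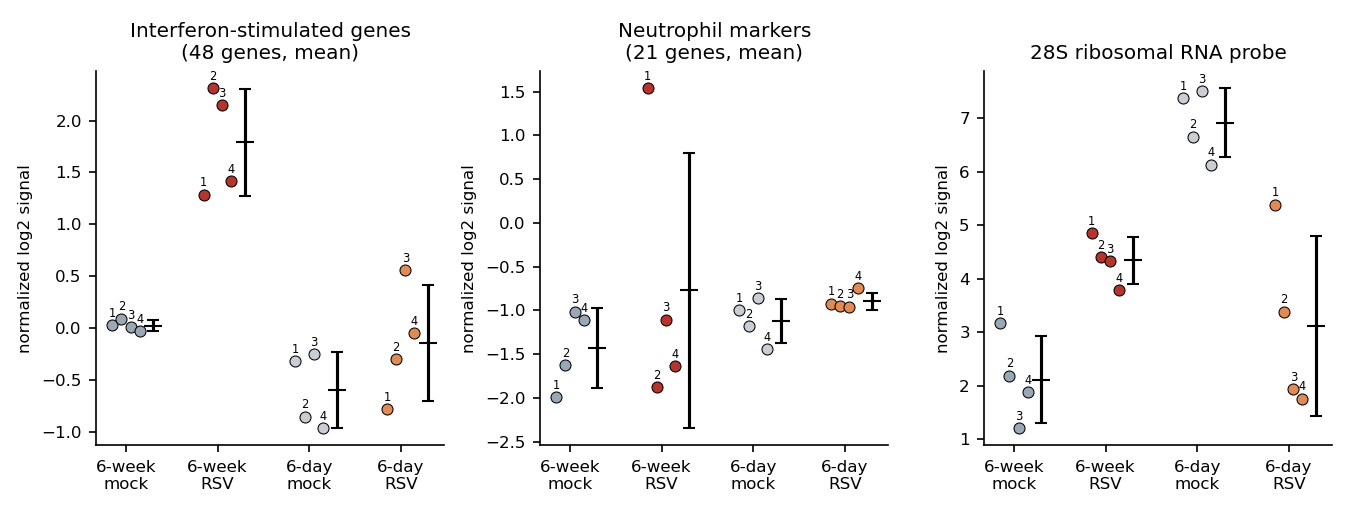
Mean normalized log2 signal of 48 interferon-stimulated genes, mean of 21 neutrophil genes and signal of the 28S probe on each of the 16 arrays, by group; points are arrays, and bars give the mean and SD. The interferon-stimulated score was 1.79 ± 0.51 in 6-week RSV lungs and -0.15 ± 0.56 in 6-day RSV lungs.

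The comparison of RSV with mock lungs at 6 weeks asked which genes responded in the older animals. Antiviral genes induced by type I interferon rose. Irf7, the transcription factor that amplifies interferon production, was 15.3-fold higher with RSV (log2 3.93 ± 0.50, adjusted p 0.00183). Isg15, a ubiquitin-like antiviral protein, was 8.38-fold higher (3.07 ± 0.41), Ifit1, which binds viral RNA, 8.06-fold higher (3.01 ± 0.46), and Oas1a, which activates RNA decay, 5.66-fold higher (2.50 ± 0.47). Of 48 interferon-stimulated genes tested, 42 rose, none fell and 6 did not pass, and all 48 rose when adjusted over the list alone. Their median log2 fold change was 1.59 (camera adjusted p 6.63e-41, adjusted p = 0.145 with an estimated correlation), and within slides it was 1.27, 2.09, 2.06 and 1.16. The score rose by an exact two-sided permutation test (p = 0.0286, the smallest 4 against 4 allows; 0.107 after Benjamini-Hochberg adjustment over 30 lists). Mx1, an influenza resistance gene, was 6.02-fold higher without passing (2.59 ± 0.81, adjusted p 0.0624), and it passed in 7 of 24 other settings, among them without 6-day mock replicate 3 (2.59).

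Chemokines and acute phase genes also rose at 6 weeks. Cxcl10, which draws in T cells, was 17.6-fold higher (4.14 ± 0.54), and Cxcl11, of the same receptor, was at least 10.4-fold higher because it was below background in all 4 mock lungs. Ccl2, which recruits monocytes, was 8.63-fold higher (3.11 ± 0.43), Cxcl1, which recruits neutrophils, 4.32-fold higher (2.11 ± 0.33), and Il6 rose by log2 2.26 ± 0.31 from a mock level above background on 1 of 4 arrays. Of 28 inflammatory cytokines and chemokines 11 rose and 17 did not pass (16 rose and 1 fell when adjusted over the list alone; camera adjusted p 7.94e-09, adjusted p = 0.452 with an estimated correlation). Saa3, a serum amyloid made in inflamed lung, was 28-fold higher (4.81 ± 0.48), Saa1 18.2-fold (4.18 ± 0.36), and Lcn2, which binds bacterial iron carriers, 6.76-fold (2.76 ± 0.30). In the acute phase and airway defence list 11 of 29 genes rose and 18 did not pass (18 rose and 1 fell when adjusted over the list alone; camera adjusted p 9.27e-11, adjusted p = 0.0916 with an estimated correlation).

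The virus sensing, interferon-γ-induced, MHC class I and macrophage lists also rose by camera at 6 weeks. The 28S probe rose with RSV too (2.11 in mock and 4.34 in RSV lungs). Values of the 6-week lists with its signal as a covariate are not given. Ifih1 (1.33 ± 0.21) and Ddx58 (1.39 ± 0.22), the cytoplasmic sensors of viral RNA, were among 10 of 23 sensing genes that rose. When adjusted over the list alone 10 rose and 3 fell (camera adjusted p 0.0009, adjusted p = 0.482 with an estimated correlation). Ifih1, Ddx58, Dhx58, Irf7, Zbp1 and Trim25 are also in the interferon-stimulated list, so the sensing list is not separate from it. Its medians within slides were 0.231, 0.325, 0.137 and 0.04. Iigp1, a GTPase that attacks parasite vacuoles, rose 1.84 ± 0.39 among 6 rises and 1 fall in 27 interferon-γ-induced genes (10 and 1 when adjusted over the list alone; camera adjusted p 2.16e-05, adjusted p = 0.535 with an estimated correlation). The MHC class I list rose by a median of 0.59 (camera adjusted p 5.36e-06, adjusted p = 0.506 with an estimated correlation), with B2m, the shared light chain, the only call (1.15 ± 0.31) and 9 calls when adjusted over the list alone; B2m lost its call in 9 of 25 other settings (0.94 to 1.33), among them leaving out 6-week RSV replicate 2 (0.94) or 3 (1.07), any 6-week mock array (1.16, 1.18, 1.21 and 1.03 for replicates 1 to 4) or 6-day RSV replicate 2 (1.15). Iigp1 lost its call without 6-week RSV replicate 3 (1.65). Fcgr1, the high-affinity IgG receptor, was 4.23-fold higher (2.08 ± 0.29) and Ms4a6d 2.81-fold higher, among 9 rises in 30 macrophage and monocyte genes (15 when adjusted over the list alone; camera adjusted p 7.94e-09, adjusted p = 0.0916 with an estimated correlation). Tslp, an epithelial cytokine that starts type 2 immunity, and its receptor Crlf2 were the 2 calls of 24 type 2 genes (0.40 ± 0.10 and 0.46 ± 0.12; 3 when adjusted over the list alone; camera adjusted p 0.0797), and they lost their calls in 8 and 6 of 25 other settings. Both did so without 6-week RSV replicate 2 (0.34 and 0.43) or any 6-week mock array (0.38 to 0.42 and 0.43 to 0.49), Tslp also without 6-week RSV replicate 4 (0.35) and Crlf2 without replicate 3 (0.41).

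Lymphoid and erythroid lists fell by camera at 6 weeks, with few single genes passing. Cd79a, of the B cell receptor, fell 2.76-fold (-1.47 ± 0.35, a call lost in 5 of 25 other settings). Of 20 B cell genes 2 fell (1 higher and 10 lower when adjusted over the list alone; camera adjusted p 2.16e-05, adjusted p = 0.502 with an estimated correlation). Cd27, a co-stimulatory receptor, was the single fall of 26 T cell genes, both over all genes and when adjusted over the list alone (-0.95 ± 0.24, lost in 5 of 25; list median -0.51, camera adjusted p 5.85e-4, adjusted p = 0.535 with an estimated correlation). Of 17 erythroid genes 3 fell (4 when adjusted over the list alone; camera adjusted p 0.00117, adjusted p = 0.452 with an estimated correlation). The list of NK and cytotoxic genes fell by camera (median -0.65, adjusted p 0.0323, adjusted p = 0.747 with an estimated correlation) with no gene of 19 passing in limma over all genes or when adjusted over the list alone and 1 at an unadjusted p under 0.05. That call was lost in 5 of 25 other settings (medians -0.96 to -0.23), among them leaving out 6-week RSV replicate 1 or 3 or 6-week mock replicate 3. On the slides of replicates 1 and 3, whose RSV lungs had the male pattern, the NK medians were -1.87 and -1.24 and the T cell medians -0.75 and -0.92. On those of replicates 2 and 4 they were 0.05 and 0.14 for NK genes, and -0.10 and -0.12 for T cells. Cd79a and Cd27 lost their calls without 6-week RSV replicate 1 (-1.32 and -0.76) or 3 (-1.27 and -0.87) or 6-week mock replicate 2 (-1.38 and -0.93), 3 (-1.34 and -0.89) or 4 (-1.35 and -0.89).

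Stress and inhibitory lists rose at 6 weeks, while structural lists did not pass camera. Lgals9, a galectin that restrains T cells, rose 0.87 ± 0.19 among 4 rises and 1 fall in 24 regulatory genes (7 and 1 when adjusted over the list alone; camera adjusted p 0.00336, adjusted p = 0.482 with an estimated correlation). The 25 glucocorticoid and handling stress genes had 2 rises (3 when adjusted over the list alone; camera adjusted p 9.13e-4, adjusted p = 0.482 with an estimated correlation). Neutrophil genes rose by camera (median 0.66, adjusted p 0.00451, adjusted p = 0.689 with an estimated correlation), with Fpr1, a receptor for bacterial peptides, the single gene passing (0.85 ± 0.20, lost in 4 of 25; 7 when adjusted over the list alone). Without 6-week RSV replicate 1 the neutrophil median was -0.36, and that call also ended without 6-week mock replicate 1. Fpr1 lost its call without 6-week RSV replicate 1 (0.71) or 3 (0.89) or 6-week mock replicate 2 (0.81) or 3 (0.89), and Lgals9 without RSV replicate 3 (0.87) or mock replicate 4 (0.84). The cell cycle list rose by camera (median 0.12, adjusted p 0.0168, adjusted p = 0.747 with an estimated correlation) while none of its 37 genes passed in limma and 7 had an unadjusted p under 0.05; the call ended in 3 of 25 other settings, without 6-week RSV replicate 1, mock replicate 1 or mock replicate 3. Cdh5, the endothelial cadherin, fell (-0.39 ± 0.07) among 6 falls and 1 rise in 24 endothelial genes (6 and 2 when adjusted over the list alone; camera adjusted p 0.0626, fry adjusted p 0.0221). Eln, the elastin of alveolar walls, fell 2.35-fold (-1.24 ± 0.25) among 5 falls and 3 rises in 33 mesenchymal genes (8 and 4 when adjusted over the list alone; camera adjusted p 0.375).

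The remaining lists did not pass camera at 6 weeks. No dendritic cell gene of 31 passed in limma, over all genes or when adjusted over the list alone, and 7 had an unadjusted p under 0.05 (median -0.20, camera adjusted p 0.282, fry adjusted p 0.48). Flt3, the receptor of dendritic cell precursors, had a log2 fold change of -0.51 ± 0.32, Siglech, a plasmacytoid cell marker, -0.14 ± 0.70, and Itgax, the CD11c integrin, 0.22 ± 0.23, none past the threshold. Flt3 passed in 1 of 25 other settings (-0.58 to -0.27). Il13, Il33 and Ifng, with log2 fold changes of -0.07, 0.12 and -0.06, did not pass. Ifnar1, of the type I interferon receptor, was the 1 call of 13 interferon and receptor genes (0.31 ± 0.07, lost in 4 of 25, among them without 6-week RSV replicate 3 (0.30) or 6-week mock replicate 2 (0.31) or 3 (0.32); 2 when adjusted over the list alone; camera adjusted p 0.0626). The MHC class II list had 2 rises and 1 fall of 13 (median -0.18). Airway cells had 2 falls of 27 led by Tppp3 of ciliated cells (-0.56 ± 0.10), and imprinted and fetal growth genes 1 fall of 20. Alveolar epithelium had 1 rise and 1 fall of 25, and muscle 1 fall of 22. No gene passed in limma among eosinophil and mast cell, thymus, fat, liver or clock genes, which had 4, 2, 0, 1 and 3 genes at an unadjusted p under 0.05. In the alveolar, imprinted, liver and clock lists the median, mean and test differed in sign.

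At 6 weeks 1376 genes passed, 636 higher and 740 lower, and 4366 had an unadjusted p under 0.05. At least 2-fold changes were found in 177, 128 higher and 49 lower. Apod, a lipid carrier, was 22-fold higher (4.46 ± 0.58) and Ly6f 18.5-fold higher (4.21 ± 0.48). Crabp1, which binds retinoic acid, was 4.96-fold lower (-2.31 ± 0.38) and Pcgf2, of a polycomb complex, 2.88-fold lower (-1.53 ± 0.27). Crabp1 was not above background on all arrays, and its value ran from -2.75 to -0.83 over the other settings, with the call lost in 1. The count was 848 with the deposited value table, 2494 with only the 8 arrays, 97 with normexp background correction and 3594 with array weights. It was 129 with the 28S signal and 753 with the Xist signal as a covariate. The share of called genes that were higher was 46.2%, against 81.5% with the deposited value table, 86.6% with normexp and 83.7% with the 28S covariate. The number of genes passing was 895 without 6-week RSV replicate 1, 438 without RSV replicate 3, 567, 398 and 494 without 6-week mock replicates 2, 3 and 4, and 2081 without 6-day mock replicate 3.

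The comparison of RSV with mock lungs at 6 days asked the same question of the neonatal lung. Over all 16787 tested genes 2456 rose and 4123 fell, and the counts of the lists are to be read beside these. Interferon-stimulated genes rose little. Irf7 was 4.46-fold higher (2.16 ± 0.50, adjusted p 0.00409) and Ifi27l2a, a small mitochondrial interferon-induced protein, 3.82-fold higher (1.93 ± 0.42), whereas Isg15 (0.58 ± 0.41), Ifit1 (0.15 ± 0.46) and Cxcl10 (0.93 ± 0.54) did not pass. Oas1a was 2.55-fold higher (1.35 ± 0.47), a call lost in 6 of 25 other settings, among them without 6-day RSV replicates 2 (1.43), 3 (1.04) or 4 (1.22) or 6-day mock replicates 2 (1.07) or 4 (1.09), and Mx1 did not pass (1.07 ± 0.81). Without 6-day mock replicate 3, which stood apart from the other mock lungs, Mx1 passed (2.16), and it ran from -0.06 to 2.16 over 24 other settings. Of 48 genes 6 rose and 42 did not pass, and 2 rose when adjusted over the list alone (median 0.41, camera adjusted p 0.00243, adjusted p = 0.878 with an estimated correlation; exact permutation p of the score 0.171). The median was 0.00 on the slide with replicates 1 and 2 and 0.73 on that with replicates 3 and 4. Without 6-day RSV replicate 3 it was 0.20 with adjusted p 0.169, and with the 28S signal as a covariate it was -0.14.

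Antigen presentation, acute phase and macrophage lists rose at 6 days. H2-D1, a classical MHC class I chain, was 3.11-fold higher (1.64 ± 0.31), H2-Q7 2.99-fold (1.58 ± 0.32) and Tap1, the peptide transporter, 3.4-fold (1.76 ± 0.42). Of 24 MHC class I genes 12 rose and 1 fell, over all genes and when adjusted over the list alone (median 0.58, camera adjusted p 7.96e-05, adjusted p = 0.878 with an estimated correlation), and the slide medians were 0.29 and 1.03. Cfb, a complement factor, was 3.18-fold higher (1.67 ± 0.31) and Lcn2 3.48-fold (1.80 ± 0.30) among 12 rises of 29 acute phase genes (13 when adjusted over the list alone; camera adjusted p 7.96e-05, adjusted p = 0.655 with an estimated correlation). C1qb, which starts complement on antibody, was 1.96-fold higher (0.97 ± 0.15) and Cd14, a co-receptor for bacterial lipid, 1.77-fold (0.82 ± 0.12). They were among 8 rises of 30 macrophage genes, also 8 when adjusted over the list alone (camera adjusted p 0.0189, adjusted p = 0.878 with an estimated correlation), a list call lost in 4 of 25 other settings (0.12 to 0.39). The MHC class II list rose (median 0.32, camera adjusted p 0.03, adjusted p = 0.878 with an estimated correlation), with Ifi30, a lysosomal reductase, among 3 rises of 13 (0.45 ± 0.07; 2 when adjusted over the list alone), and its call was lost in 5 of 25 (0.25 to 0.44). Both list calls ended with quantile normalization and without 6-day RSV replicate 3 or 6-day mock replicate 3 or 4. The 28S probe, 13.9-fold lower with RSV, moved with these groups. With its signal as a covariate no list passed camera and the MHC class I and acute phase medians were 0.08 and 0.26. As the 28S signals of RSV and mock arrays did not overlap, that loss cannot separate infection from what the probe follows.

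Fetal growth genes rose at 6 days and several type 2 and sensing genes fell. Dlk1, a fetal growth inhibitor of fat cells, was 6.09-fold higher (2.61 ± 0.52), H19 3.49-fold (1.80 ± 0.33) and Igf2, the fetal growth factor, 1.65-fold (0.72 ± 0.12). Of 20 imprinted and fetal growth genes 7 rose and 1 fell, also when adjusted over the list alone (median 0.33, camera adjusted p 0.00262, adjusted p = 0.249 with an estimated correlation). Slide medians were 0.37 and 0.42. With the 28S signal as a covariate the median of this list was 0.26, and it no longer passed camera. Ccl17, a chemokine of type 2 T cells, fell 1.69-fold (-0.76 ± 0.19), Il33, an epithelial alarmin, 1.37-fold (-0.45 ± 0.12) and Il13, a type 2 cytokine, 1.96-fold (-0.97 ± 0.28); Il33 and Il13 lost their calls in 1 and 3 of 25 other settings, Il13 also without 6-day RSV replicate 2 (-0.78). Of 24 type 2 genes 9 fell and 1 rose, with 11 and 2 when adjusted over the list alone (camera adjusted p 0.311, fry adjusted p 0.0303). Irf3, which switches on interferon genes, fell 1.59-fold (-0.67 ± 0.08) and Tlr4 fell 1.55-fold (-0.64 ± 0.09), against 5 rises and 3 falls of 23 sensing genes, the same numbers when adjusted over the list alone.

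Structural genes rose and fell at 6 days in lists that did not pass camera. Sftpb, of surfactant, was 2.42-fold higher (1.27 ± 0.21) and Pdpn, of flat alveolar cells, 2.17-fold (1.12 ± 0.18), with 7 rises and 2 falls in 25 alveolar genes (9 and 3 when adjusted over the list alone; camera adjusted p 0.0822, fry adjusted p 0.0414). Tie1, a vessel receptor, was 2.01-fold higher (1.01 ± 0.14) with 6 rises and 3 falls in 24 endothelial genes, also when adjusted over the list alone. Eln was 2.29-fold higher (1.20 ± 0.25) with 5 rises and 4 falls in 33 mesenchymal genes, and Krt15, of basal airway cells, 2.41-fold (1.27 ± 0.25) with 4 rises and 1 fall in 27 airway genes. Cell cycle genes had 9 falls of 37, including Cenpe, a mitotic motor (-0.82 ± 0.16, lost in 1 of 25), and 5 when adjusted over the list alone. That is close to the share of falls over all tested genes, 4123 of 16787. Tgfb1, an inhibitory cytokine, was 2.30-fold higher (1.20 ± 0.22) with 4 rises and 2 falls in 24 regulatory genes. Dendritic cell genes had 2 rises and 5 falls of 31 (1 fall when adjusted over the list alone), with Flt3 (-0.77 ± 0.32), Siglech (-0.66 ± 0.70) and Itgax (-0.13 ± 0.23) not past the threshold. Flt3 passed in 3 of 25 other settings (-1.12 to -0.42), and Siglech was above background on 1 of 4 arrays in each 6-day group.

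The other lists did not pass camera at 6 days. Inflammatory genes had 3 rises of 28, led by Il1rn, which blocks interleukin-1 (0.80 ± 0.23), and no call in limma when adjusted over the list alone, with 6 at an unadjusted p under 0.05 (fry adjusted p 0.965); Ccl2 (0.05 ± 0.43) and Cxcl1 (0.21 ± 0.33) did not pass, and Il6 was below background on all 6-day arrays. Cd177, of neutrophils, was the single rise of 21 (3.04-fold, 1.61 ± 0.36), and T cells had 1 rise. No NK or erythroid gene passed in limma, with 0 and 3 at an unadjusted p under 0.05 (fry adjusted p 0.986 and 0.114). Interferon-γ-induced genes had 4 rises and 2 falls of 27 (median 0.45, camera adjusted p 0.056), and interferons and their receptors 2 falls of 13. B cells had 2 rises and 1 fall, and eosinophil and mast cell genes 2 rises and 1 fall. Muscle had 3 rises and 2 falls, thymus 3 falls, fat 1 fall, and liver 1 rise and 1 fall. Nr1d1, a clock repressor, was 4.27-fold higher (2.10 ± 0.33, call lost in 1 of 25) with 3 rises and 1 fall in 16 clock genes. Atf3, a stress factor, was 2.18-fold higher (1.12 ± 0.16) with 5 rises and 3 falls of 25 stress genes. Median, mean and test differed in sign for T cells, NK cells, endothelium, mesenchyme, eosinophils, clock and muscle. The liver list, a check of sample make-up, had a score difference of -0.926 with RSV (exact permutation p 0.0286, 0.143 after adjustment). Its highest 6-day score was on mock replicate 3 (-2.16), and a difference in sample make-up was not tested.

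At 6 days 6579 genes passed, 2456 higher and 4123 lower, and 8224 had an unadjusted p under 0.05. At least 2-fold changes were found in 541, 232 higher and 309 lower. H2-D4 was 3.74-fold higher (1.90 ± 0.37), while Fabp1, a fatty acid carrier, was 5.05-fold lower (-2.34 ± 0.27) and Gjd3, a gap junction protein, 5.19-fold lower (-2.38 ± 0.46). The median of all genes was -0.13, against -0.01 with quantile normalization, which gave 49.7% of called genes higher in place of 37.3%, and 0.02 with the deposited value table, which gave 68.2%. Of 3317 called genes with another tested probe, 481 had one called in the opposite direction, against 6 of 660 at 6 weeks. The count was 4189 with only the 8 arrays, 2457 with normexp, 10948 with array weights and 2 with the 28S covariate, under which 1612 had an unadjusted p under 0.05 and the median standard error rose from 0.142 to 0.247.

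The difference of the responses, 6 days minus 6 weeks, asked whether the neonatal response differed. Over all 16787 tested genes 2881 had a higher and 3903 a lower response at 6 days, and list counts are to be read beside these. Interferon-stimulated genes responded less at 6 days. The log2 difference was -2.49 ± 0.58 for Isg15 (adjusted p 0.00414), -2.86 ± 0.65 for Ifit1, -1.63 ± 0.32 for Ddx58 and -3.21 ± 0.76 for Cxcl10. Irf7 (-1.78 ± 0.70, adjusted p 0.0567), Oas1a (-1.15 ± 0.67) and Mx1 (-1.52 ± 1.15) did not pass, though Irf7 passed in 6 of 24 other settings (range over all 24 -2.17 to -1.33), among them without 6-week RSV replicate 1 (-2.17), 6-day RSV replicate 3 (-2.08) or 6-day mock replicate 4 (-1.95). Of 48 genes 26 had a lower response and 22 did not pass, with 36 lower when adjusted over the list alone (median -1.35, camera adjusted p 2.13e-06, adjusted p = 0.915 with an estimated correlation; fry adjusted p 0.0581). The permutation test of the score difference gave p 0.109 (exact). B cell genes differed in the other direction, with Cd79a at 1.84 ± 0.49 among 5 of 20 (4 when adjusted over the list alone; median 0.79, camera adjusted p 0.0305, adjusted p = 0.915 with an estimated correlation), a list call lost in 6 of 24 other settings (0.54 to 1.06). These were quantile normalization and leaving out 6-week RSV replicate 1, 6-week mock replicate 2, 6-day RSV replicate 1 or 2, or 6-day mock replicate 4.

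**Figure D2:**
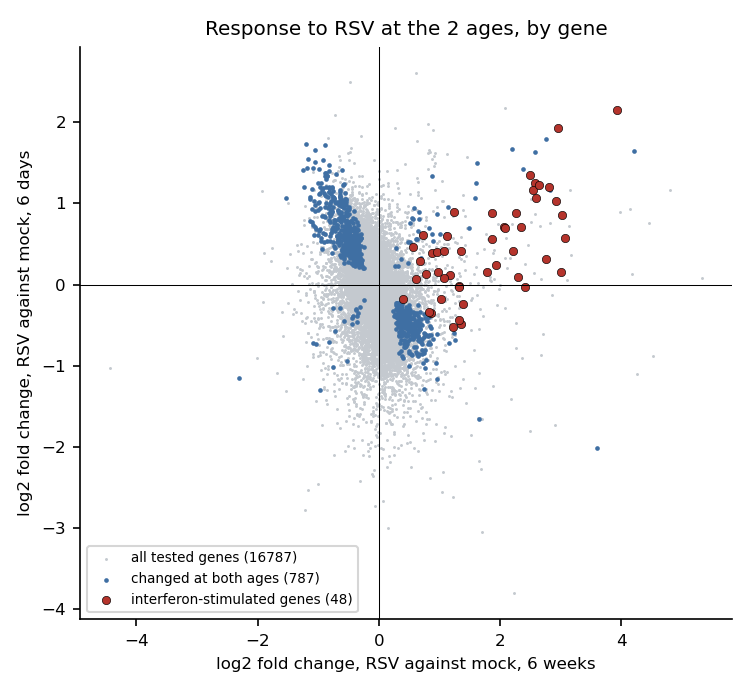
Log2 fold change with infection at 6 weeks (horizontal) and 6 days (vertical) of 16787 genes, with the 787 changed at both ages and 48 interferon-stimulated genes marked. The responses had a correlation of -0.283 across genes, which are not independent replicates.

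Some inflammatory and acute phase genes also responded less at 6 days, in lists that did not pass camera. Saa1, Saa2 and Saa3 differed by -4.05 ± 0.51, -5.42 ± 0.75 and -3.64 ± 0.68, Ccl2 by -3.05 ± 0.61, Cxcl1 by -1.90 ± 0.46 and Csf2, a growth factor of myeloid cells, by -1.30 ± 0.24. Il6 was below background on all 6-day arrays, so no difference is given. Of 28 inflammatory genes 10 responded less and 18 did not pass (camera adjusted p 0.106), and of 29 acute phase genes 6 responded less, 3 more and 20 did not pass (camera adjusted p 0.742). Of 24 type 2 genes 10 responded less, also when adjusted over the list alone, including Ccl17 (-1.38 ± 0.27) and Retnla, of alternatively activated macrophages (-2.14 ± 0.49). Their score difference was -0.669 (exact permutation p 0.00327, 0.049 after adjustment, camera adjusted p 0.207). That permutation tests for no infection effect at either age, so it cannot show that the responses differ. At 6 weeks alone the score rose (exact permutation p 0.0286, 0.107 after adjustment). At 6 days alone it fell without passing (exact permutation p 0.143, 0.39 after adjustment), and 6-day mock replicate 4 (-1.48) lay below every 6-day RSV array. Tlr4 (-1.01 ± 0.12) and Irf3 (-0.75 ± 0.11) were among 7 sensing genes of 23 with a lower response, and 5 had a higher one.

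Single structural genes responded more at 6 days, in lists that did not pass camera. With the 28S signal as a covariate no gene of this contrast passed in limma, and 1405 had an unadjusted p under 0.05. Values of the named genes under that covariate are not given. Tie1 differed by 1.61 ± 0.19 and Flt4, a lymphatic vessel receptor, by 2.03 ± 0.31, with 8 higher and 4 lower of 24 endothelial genes. The endothelial score difference was 0.289 (exact permutation p 0.00204, 0.049 after adjustment, camera adjusted p 0.213). As for the type 2 score, this permutation cannot show that the responses differ. Eln differed by 2.43 ± 0.35 with 7 higher and 5 lower of 33 mesenchymal genes, Sftpb by 1.77 ± 0.30 with 9 higher and 3 lower of 25 alveolar genes, and Tppp3 by 1.19 ± 0.14 with 4 higher and 1 lower of 27 airway genes. H19 differed by 2.64 ± 0.47 with 8 higher and 2 lower of 20 imprinted and fetal growth genes (camera adjusted p 0.106, fry adjusted p 0.0129). Aurkb, a mitotic kinase, was among 10 of 37 cell cycle genes with a lower response (-1.15 ± 0.26). T cells had 6 higher, including Zap70 (1.01 ± 0.29), NK cells 1 higher, and macrophages 7 lower and 1 higher, led by Fcgr1 (-1.75 ± 0.41). Tgfb1 differed by 1.97 ± 0.31 with 1 higher and 2 lower of 24 regulatory genes.

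The remaining lists did not pass camera. Interferon-γ-induced genes had 1 higher and 4 lower, interferons and their receptors 4 lower, and dendritic cells 2 higher and 4 lower. MHC class I genes had 2 lower, MHC class II genes 2 higher and 1 lower, and neutrophils 1 lower, Fpr1 (-1.25 ± 0.28). Eosinophil and mast cell genes had 2 higher, Kit and Gata2, erythroid genes 1 of each, muscle 5 higher and 2 lower, thymus 2 of each, liver 1 higher and 2 lower, clock genes 2 higher and 1 lower, and stress genes 4 higher and 5 lower. No fat gene of 13 passed in limma, and 0 had an unadjusted p under 0.05 (fry adjusted p 0.289). Flt3 (-0.26 ± 0.45), Siglech (-0.52 ± 0.99), Itgax (-0.35 ± 0.33), Ifng (0.04 ± 0.96) and Il13 (-0.90 ± 0.40) did not pass, and Il33 did (-0.57 ± 0.17).

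**Figure D3:**
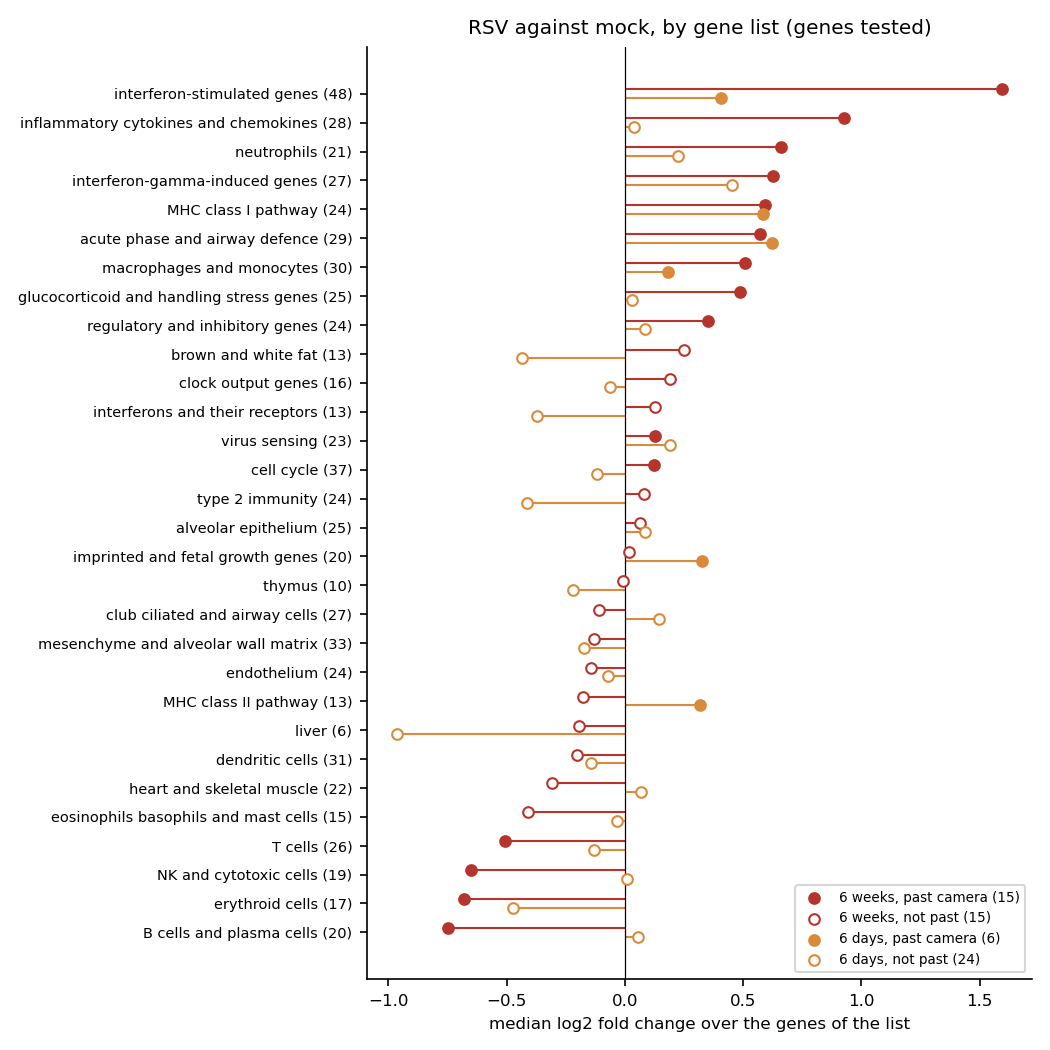
Median log2 fold change of each gene list with infection at 6 weeks and at 6 days; filled points passed camera. At 6 weeks 15 of 30 lists passed camera and at 6 days 6 of 30, but 0 and 0 did with an estimated correlation, where 3 and 2 had an unadjusted p under 0.05, and 8 and 5 passed fry.

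The responses differed in 6784 genes, 2881 higher and 3903 lower at 6 days, and 8175 had an unadjusted p under 0.05. At least 2-fold differences were found in 1789, 864 higher and 925 lower. Among 3459 called genes with another tested probe, 499 had one called in the opposite direction. Itga5, an integrin for fibronectin, differed by 2.92 ± 0.39 and Jup, a junction protein, by 2.71 ± 0.38. Of genes changed at both ages, 448 were lower at 6 weeks and higher at 6 days where 108.3 were expected if independent, 277 were higher then lower (156.2 expected), 41 higher at both (93) and 21 lower at both (181.7). Across the interferon-stimulated genes the correlation of responses was 0.67. The 28S response differed by -6.03 ± 0.93. With the 28S signal as a covariate no gene passed in limma and 1405 had an unadjusted p under 0.05; the count was 2345 with normexp, 4512 with the value table and 10204 with array weights. The share of called genes that were higher at 6 days was 42.5%, against 51.3% with quantile normalization and 55.1% with the value table, so the majority direction turned.

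The comparison of mock lungs at 6 days with those at 6 weeks asked how the uninfected lung differed with age. Age here cannot be told apart from array batch. Over all 16787 tested genes 5843 were higher and 4440 lower at 6 days, and list counts are to be read beside these. Growth and matrix genes were higher at 6 days. Top2a, which untangles replicating DNA, was 6.64-fold higher (2.73 ± 0.15, adjusted p 3.49e-09), Tnc, a matrix protein of developing tissue, 31.9-fold (adjusted p 1.92e-11), Mest, an imprinted growth gene, 14.9-fold (3.89 ± 0.14), and Slc4a1, the red cell anion channel, 14.7-fold (3.88 ± 0.31). All 37 cell cycle genes were higher (median 1.84, camera adjusted p 3.92e-14, adjusted p = 0.267 with an estimated correlation). Of 33 mesenchymal genes 24 were higher and 2 lower (camera adjusted p 3.99e-06, adjusted p = 0.139 with an estimated correlation). Of 20 imprinted and fetal growth genes 17 were higher and 1 lower (camera adjusted p 3.99e-06, adjusted p = 0.0254 with an estimated correlation). Erythroid genes had 15 higher and 1 lower of 17 (camera adjusted p 1.91e-05, adjusted p = 0.132 with an estimated correlation). The counts adjusted over the list alone were 37, 25, 17 and 15 higher in these lists.

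Airway, alveolar and defence genes were lower at 6 days. Bpifa1, an airway defence protein, was 139.0-fold lower (-7.12 ± 0.36), Aldh1a1, a detoxifying enzyme of club cells, 7.16-fold (-2.84 ± 0.18), Sftpb 4.78-fold (-2.26 ± 0.21) and Hp, which binds free haemoglobin, 7.02-fold (-2.81 ± 0.10). Airway cells had 23 of 27 lower (24 when adjusted over the list alone; camera adjusted p 2.88e-10, adjusted p = 0.0692 with an estimated correlation), alveolar epithelium 18 lower and 3 higher of 25 (camera adjusted p 6.9e-05, adjusted p = 0.103 with an estimated correlation) and acute phase genes 22 lower and 1 higher of 29 (camera adjusted p 2.59e-07, adjusted p = 0.132 with an estimated correlation). Plvap, of vessel pores, was 3.64-fold lower (-1.86 ± 0.14), with 11 lower and 4 higher of 24 endothelial genes (camera adjusted p 0.0429, adjusted p = 0.398 with an estimated correlation).

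Immune genes were lower at 6 days. H2-Eb1, an MHC class II chain, was 4.53-fold lower (-2.18 ± 0.22), H2-D1 4.47-fold (-2.16 ± 0.31), Nkg7, of cytotoxic granules, 4.52-fold (-2.17 ± 0.45) and Itgae, of CD103 dendritic and T cells, 5.69-fold (-2.51 ± 0.26). MHC class II genes had 12 of 13 lower (13 when adjusted over the list alone; adjusted p 5.7e-05 by camera, adjusted p = 0.398 with an estimated correlation), MHC class I genes 20 of 24 (5.7e-05, adjusted p = 0.524 with an estimated correlation), NK genes 13 of 19 (1.75e-4, adjusted p = 0.524 with an estimated correlation) and macrophages 18 lower and 2 higher of 30 (7.71e-05, adjusted p = 0.132 with an estimated correlation). Dendritic cell genes had 15 lower and 4 higher of 31 (0.0207, adjusted p = 0.579 with an estimated correlation). Fscn1, of mature cells, was 5.47-fold higher (2.45 ± 0.28) and Itgax 2.47-fold lower (-1.30 ± 0.23), whereas Flt3 (0.25 ± 0.32) and Siglech (-1.62 ± 0.70) did not pass. Siglech was above background on 1 of 4 6-day mock arrays. Interferon-stimulated genes had 21 lower and 1 higher of 48 (median -0.71, camera adjusted p 4.02e-4, adjusted p = 0.579 with an estimated correlation). The exception was Rsad2, viperin, 7.83-fold higher (2.97 ± 0.25); Isg15, Irf7, Mx1 and Ifit1 did not pass.

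**Figure D4:**
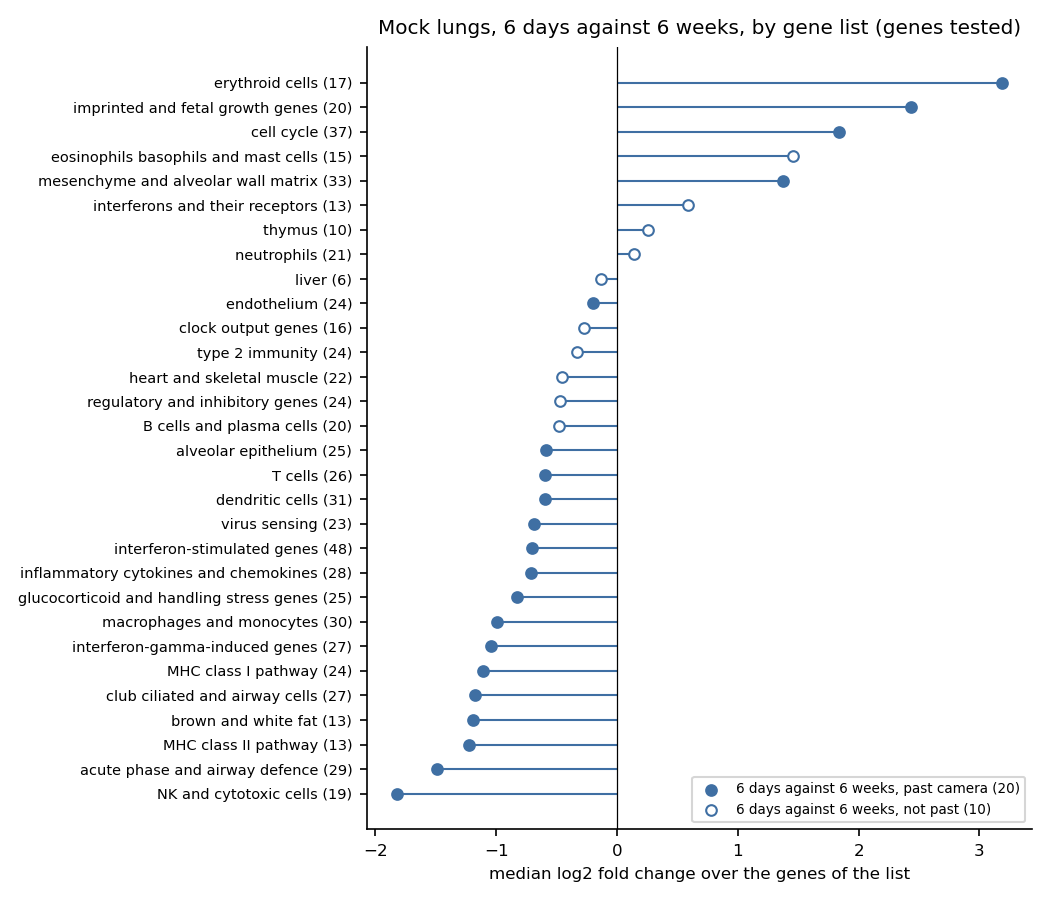
Median log2 difference of each gene list between mock lungs at 6 days and 6 weeks; filled points passed camera. The list of imprinted and fetal growth genes, with a median of 2.44, was the 1 list that passed with an estimated correlation.

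The other lists varied. Interferon-γ-induced genes had 16 lower and 2 higher of 27 (camera adjusted p 0.00332, adjusted p = 0.579 with an estimated correlation), virus sensing 14 lower and 2 higher of 23, among them Mavs (-0.72 ± 0.08) (0.00252, adjusted p = 0.423 with an estimated correlation), inflammatory genes 14 lower and 2 higher of 28 (0.00838, adjusted p = 0.579 with an estimated correlation), T cells 11 lower and 2 higher of 26 (0.0222, adjusted p = 0.579 with an estimated correlation), fat 8 lower and 1 higher of 13 (0.0101, adjusted p = 0.556 with an estimated correlation) and stress genes 15 lower and 2 higher of 25 (0.00325, adjusted p = 0.398 with an estimated correlation). Not past camera were B cells (5 lower) and neutrophils (7 lower, 3 higher, with median 0.14 against a test pointing down). The same held for type 2 genes (10 lower, 6 higher), regulatory genes (11 lower, 6 higher) and muscle (9 lower, 5 higher). Interferons and their receptors (7 higher, 3 lower) and thymus (4 higher, 1 lower) did not pass either. Nor did liver (2 lower, 1 higher) or clock genes (4 lower, 3 higher). Eosinophil and mast cell genes had 9 higher and 4 lower of 15 (median 1.46, camera adjusted p 0.341, fry adjusted p 0.00111), with Mcpt4, a mast cell protease, 4.78-fold higher (2.26 ± 0.28). Il13 was 2.88-fold higher (1.53 ± 0.28) and Il33 1.58-fold lower (-0.66 ± 0.12). The inflammatory, dendritic, T cell and fat calls ended with the deposited value table, the dendritic and T cell calls also without 6-day mock replicate 4, and the endothelial call with quantile normalization or without 6-week mock replicate 2 or 6-day mock replicate 3. The dendritic and endothelial calls also ended with only genes above background on all arrays.

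Between mock lungs 10283 genes passed, 5843 higher and 4440 lower at 6 days. At least 2-fold differences were found in 3972, 2461 higher and 1511 lower. Among 4484 called genes with another tested probe, 466 had one called in the opposite direction. Lrrc15, a mesenchymal membrane protein, was at least 176.0-fold higher and Cyp1a1, a detoxifying enzyme, at least 82.2-fold lower, each against a group below background. The deposited value table gave 32% of called genes higher and quantile normalization 47.3%, in place of 56.8%. The median of all genes was 0.08, against -0.24 with that table and -0.03 with quantile normalization, and 3151 genes passed with the 28S signal as a covariate.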

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

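The tests of the neutrophil pattern and 2 of the 28S tests, those in mock arrays alone and as the whole cause, were chosen only after the results were seen. Of 184 groups of 4 arrays examined for a single array far from its group, 14 had one, where chance gives about 9.2.

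The responses to infection at the ages compared differed in 6784 genes, and genes tended to move in opposite directions, with a correlation across genes of -0.283. Against uneven numbers of males and females, the correlation was -0.30 with the Xist signal as a covariate, and against probe GC content it was -0.267 after correction. RNA quality or labelling that the 28S probe follows may contribute: the slope of genes on the 28S signal within groups had a correlation of -0.573 with the 6-day response (permutation p 0.002) and 0.221 with the 6-week response (permutation p 0.033). In mock arrays alone these were -0.588 (p 0.00999) and 0.232 (p 0.0619), which leaves that test open, and the covariance of the responses after the covariate and slope error were removed was 0.0328 against -0.0564 before, although the plain correlation with the covariate was still -0.321. RNA quality therefore remains a candidate for this pattern, beside a biological difference between the ages that was not tested apart from it.

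Interferon-stimulated genes responded less at 6 days by camera, with a median difference of -1.35, a call that did not hold with an estimated correlation (adjusted p = 0.915). A narrower range of signal on the 6-day arrays is argued against by a spread ratio of 0.953 over 14653 genes, and uneven sexes by a median of -1.50 with the Xist covariate. The 28S axis predicts a change of 0.65, within the -1.36 to 1.19 given by shuffled signals (p 0.788), so it cannot be told apart from no effect. Age itself may explain the lower response, but age stays confounded with array batch between groups of arrays.

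On 6-week RSV replicate 1 the alveolar score was far from the rest of its group at 3.80. Its neutrophil score was the highest of the group at 1.54, with a gap to the others below the limit used for single arrays. Against blood left in the lung, its erythroid score differed from the rest of its group by 0.05. For the sex of the animal, the other 3 male arrays differed from the females of their groups by 0.06 on average, but in different directions. Of these, 6-week RSV replicate 3 (-1.11) was above its females (-1.88 and -1.64). The score of 6-day mock replicate 4 (-1.44) was below its females, and that of 6-day RSV replicate 1 (-0.92) lay among them. This mean therefore cannot decide about sex. Against a swap with a mock array, the interferon-stimulated score of 6-week RSV replicate 1 was 1.2 above the highest 6-week mock array. No biological explanation was tested.

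Real groupings were set against other splits of the same arrays. At 6 weeks 1376 genes passed against at most 1 in another split (1 of 35 splits as large), and for age in mock lungs 10283 against 2 (1 of 35). A share of 1 in 35 is the smallest these splits allow, so chance is unlikely in both but not excluded. At 6 days, 6579 genes stood against 3986 (1 of 35). The split with 3986 exchanged 6-day RSV replicate 1 and 6-day mock replicate 4. Both had the male pattern, so the exchange left the balance of males as in the real grouping. With the Xist signal as a covariate the real grouping gave 6471 genes. The exchanged arrays had the highest 28S signal of the 6-day RSV arrays (5.38) and the lowest of the 6-day mock arrays (6.13). Whether the 28S signal lay behind the 3986 genes was not tested. Another split gave 495, and the split by slide gave 65. The real grouping gave the most genes, but chance was not excluded. For the difference of responses, 6784 stood against 4932 (1 of 100 drawn splits). These splits exchanged labels within each age, so they test for no infection effect at either age. A response at 1 age alone could make 6784 the largest, so they cannot decide whether the responses differ.

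The B cell responses differed by a median of 0.79 by camera, which did not hold with an estimated correlation (adjusted p = 0.915) or in 6 of 24 other settings. The responses also had score differences of -0.669 for type 2 immunity and 0.289 for endothelium. Their permutation test refers to no infection effect at either age and cannot show that the responses differ. Arrays far from their group were 6-day RSV replicate 4 for interferons and their receptors (-2.00) and neutrophils (-0.75). So was 6-day mock replicate 3 for NK cells (-2.91), eosinophils and mast cells (-1.39), clock genes (-0.76) and Mx1 (-3.23). Others were 6-day RSV replicate 2 for eosinophils and mast cells (-1.56) and Il13 (-5.28), and 6-day mock replicate 1 for erythroid cells (-0.41). The rest were 6-week mock replicate 2 for fat (0.00) and Cxcl10 (-2.45), 6-week RSV replicate 1 for Ifng (-6.51), and 6-week mock replicate 4 for Il33 (1.21). Among probes without a gene name, which no comparison used, 87 changed with infection at 6 weeks and 702 at 6 days.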

How the results depend on the processing

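Normexp, the 28S and Xist covariates, array weights and leaving out the arrays standing apart together were chosen after seeing the data. Under the settings fixed before the data were examined 238 of 332 gene results stayed on the same side of the threshold, 76 lost the call somewhere, 17 gained it and 1 called result reversed. Several results that did not pass changed sign, among them Ccl2 (-0.08 to 0.22) and Ifit1 (-0.19 to 0.47) at 6 days. The interferon-stimulated camera call at 6 weeks held in all 25 (median 1.39 to 1.77), but not with an estimated correlation (adjusted p 0.145). Where no cause is given, the cause was not tested.

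Genes passing at 6 weeks were 848 with the value table, 2494 with only the 8 arrays, 97 with normexp, 129 with the 28S covariate, 753 with the Xist covariate and 3594 with array weights; leaving out an array gave 398 (6-week mock replicate 3) to 2081 (6-day mock replicate 3). At 6 days they were 4189 with only the 8 arrays, 2457 with normexp, 2 with the 28S covariate and 10948 with array weights. For the difference of responses they were 4512 with the value table, 2345 with normexp, 0 in limma with the 28S covariate (1405 at unadjusted p under 0.05) and 10204 with array weights. For age, 3151 passed with the 28S covariate. A 2-fold minimum, stricter by construction, left 177, 541, 1789 and 3972. With a replicate block the counts were 1276, 6770, 6892 and 10365.

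Lists past camera at 6 days were 11 without the filter, 11 with normexp, 0 with the 28S covariate, and 3 (without 6-day RSV replicate 3) to 8 (without 6-day RSV replicate 1). For the difference of responses they were 1 with quantile normalization, 4 with the value table, 5 without the filter, 5 with the mean of probes, 5 with normexp, 8 with the 28S covariate, and 1 (without 6-week mock replicate 2) to 3 (without 6-week RSV replicate 4). For age, 11 passed with the 28S covariate. The interferon-stimulated median at 6 days reversed to -0.14 with the 28S covariate and ran from 0.20 (without 6-day RSV replicate 3) to 0.51 (without 6-day RSV replicate 1).

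Reversed genes were Icam1 at 6 days with the mean of probes (0.083), and with normexp Nos2 (-0.47), Cxcl5 (-0.47), Tnf (-0.37) and Tcte1 (-0.11) at 6 days, Nos2 for the difference of responses (-0.04) and Cxcl1 for age (0.075). Normexp on the mean signal was not run because the 6-day files do not hold it, and lists for age were not run with slide as a random block. Signal over background limits genes such as Ifnb1 and Il10, above background on 2 arrays each and not tested.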

Other observations

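Values here come from the comparison of mock lungs and were picked after they were seen. At 6 days Tpsab1, a mast cell tryptase, was at least 7.52-fold higher and Vcan, a matrix proteoglycan, 19.3-fold higher (4.27 ± 0.26), while Chil3, a chitinase-like protein of alveolar macrophages, was 13.8-fold lower (-3.78 ± 0.51). Tgfb2, a growth inhibitor of epithelium, was 5.07-fold higher (2.34 ± 0.18) and Cd274, the ligand PD-L1, 3.78-fold lower (-1.92 ± 0.33). The cytosolic DNA sensor Cgas was 1.83-fold higher (0.87 ± 0.11), whereas its partner Sting1 was 1.61-fold lower (-0.69 ± 0.10). Tcf7, of immature T cells, was 1.89-fold higher (0.92 ± 0.15) and Zap70, a T cell receptor kinase, 2.48-fold lower (-1.31 ± 0.20).

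Ifnb1 was above background on 2 arrays, 6-week RSV replicate 1 and 6-day mock replicate 1, and Ifna4 on 1, a 6-day mock array. Ifnl2 had no named probe. The lowest array weight was that of 6-day mock replicate 3, 0.126.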
